A study of Homo sapiens with 12 samples.

How the data were processed

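Polyadenylated RNA was sequenced from SUM149PT, an established cell line from an inflammatory breast cancer that lacks hormone receptors and ERBB2 amplification. Per the labels' protocols, cells were held in 5 µM tazemetostat, an inhibitor of the histone methyltransferase EZH2, or in DMSO from day -5, with passages on day -3 and day -1. At the last passage 250000 cells were plated per 6 cm dish. On day 0 the medium was changed to 2% serum with 5 µM ipatasertib, an inhibitor of the AKT kinases, tazemetostat, both or neither, and RNA was collected after 24 h. The tazemetostat exposure was therefore longer than the ipatasertib exposure in every group that had it. Libraries were made with the Kapa Hyper Prep kit, per the labels. The labels name 4 groups of 3 libraries with the replicate letters A, B and C, giving 12 libraries. They do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

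The authors aligned the reads and counted them per gene, and deposited raw counts for each library. Per the submitters' processing notes, STAR, SAMtools, HTSeq and DESeq2 were used with the genome build hg19. Versions, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and no coordinates are given. The counts were used as deposited, under the gene symbols of the files, for 23228 genes. The 5 summary lines that name no gene were left out of library sizes and tests, and held 29.8% to 38.6% of the reads of a library. Gene counts summed to 22355242 to 49970540 per library, so 3 counts, the limit that a count of 0 allows, came to between 0.0600 and 0.134 CPM, the usual unit of counts scaled to a common library size. These limits cover counting error only. The authors also deposited a table of normalised signal for the whole series. Of its 23228 lines, 23202 could be matched by symbol, and each library's values equalled its counts divided by 1 size factor within a relative tolerance of 1e-06. The other 26 carried dates in place of symbols. This table served to check the counts and was not tested. Every one of its sample columns was matched to a labelled library.

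Replicates were first compared with a chi-square test of their counts. The statistic per degree of freedom lay between 2.70 and 26.2, above counting error in every pair, which repeats of 1 sample can also be. Each library counted as 1 replicate, as the labels give them. Tazemetostat A and combination B stood apart from the other libraries of their groups, with 18.2 to 20.1 and 15.1 to 26.2. Counts were then analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr, which left 14874 genes, and libraries were scaled with TMM factors. All 12 libraries entered 1 quasi-likelihood fit with 1 coefficient per group and no block, and the common biological coefficient of variation was 0.0645. The quasi-likelihood F-test was applied to 6 comparisons, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The 6 comparisons were each treatment group against DMSO, the combination against each inhibitor alone, and the interaction, which is the log2 change in the combination minus the sum of the log2 changes with each inhibitor. Genes apart in the combination were called by an intersection-union test, with the largest of the 3 p-values of the combination against DMSO, ipatasertib and tazemetostat, for genes with 1 direction in all 3. The overlap of the responses to each inhibitor was counted per direction, and set beside the overlap of independent lists and 20 simulated draws of unchanged groups that shared the DMSO libraries.

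Before the data were examined, 24 gene lists were fixed. They were PI3K-AKT-FOXO feedback, cholesterol synthesis, fatty acid synthesis, glycolysis, ribosome biogenesis, DNA replication and S phase, mitosis, luminal markers, basal and myoepithelial markers, mammary involution, milk and alveolar secretion, the BCL2 family, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory cytokines, PRC2 subunits, HOX genes, other developmental transcription factors, the ATF4 and amino acid response, autophagy and lysosome, ERK feedback and immediate early genes, epithelial-mesenchymal transition, markers of other cell types, and mitochondrially encoded transcripts. None of the 13 mitochondrial symbols was found in the files used here, which left 23 lists. Counts of members below are out of those that passed the filter. For some lists these were far fewer than the genes fixed. They were 8 of 17 for milk and alveolar secretion, 10 of 17 for markers of other cell types and 22 of 30 for luminal markers. For HOX genes they were 23 of 39, and for other developmental transcription factors 55 of 76. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted with the Benjamini-Hochberg method over the lists of a comparison. A preset panel of 25 genes, of which 24 passed the filter, was read gene by gene.

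The rule for named genes was also fixed then. It took, in each comparison, the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 5 CPM over the 12 libraries. In the pairwise comparisons the libraries of both groups also had to be fully separated, which a given unchanged gene meets by chance in 10% of cases with 3 against 3. Clone names, antisense genes and pseudogenes were passed over. The rule added up to 4 members of each list with the smallest p, the preset panel, the 6 highest and 6 lowest genes apart in the combination, and 4 genes called in opposite directions by the inhibitors. Some genes that the rule names are not reported here, and they stayed in the fits and lists. With 3 libraries against 3, an exact permutation test of a single value cannot give a p below 0.1, so none was run per gene.

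The steps were first tested on simulated data drawn from the real means and library sizes, with 200 genes changed. For ipatasertib against DMSO, 14673 genes were tested, 87% of the genes changed 1.5-fold and 93% of those changed 2-fold were recovered, and 5 of 185 calls were false. In the same data 11 of 190 calls were false for the combination against DMSO and 10 of 191 against tazemetostat. For an interaction simulated over 14682 genes the shares were 67% and 86%, with 10 of 163 calls false. For genes apart in the combination over the same 14682 genes they were 79% and 92%, with 0 false calls. There 14 of 189 calls were false for the combination against ipatasertib, and 12 of 194 for tazemetostat against DMSO in a further draw. All simulated libraries shared 1 dispersion per gene, so libraries that stand apart from their group were not simulated. The 200 changes were also balanced between rises and falls. The pairwise comparisons below called 39.1% to 71.0% of the genes tested, so library scaling under such broad changes was not tested by these draws. For the lists, 1 of 1 planted list and 0 of 20 unchanged lists were called in the interaction, over 14874 genes. The simulated genes varied independently of each other. The 0 therefore does not measure false calls for lists whose members are correlated, as measured genes can be.

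The alternatives fixed before the data were examined were DESeq2 size factors in place of TMM, no filter and a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0 as the test, a fit of the compared groups only, the replicate letter as a block, a test against a 1.5-fold change with glmTreat, and leaving out each library. Scaling by total counts alone, and leaving out tazemetostat A and combination B together, were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.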

Results

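Gene expression was measured by RNA sequencing in SUM149PT breast cancer cells under DMSO, the AKT inhibitor ipatasertib, the EZH2 inhibitor tazemetostat, or both inhibitors, with 3 libraries in each of the 4 groups. The libraries held 22355242 to 49970540 gene counts, with 32470808 to 44924160 under DMSO, 22355242 to 39001543 with ipatasertib, 43226082 to 49970540 with tazemetostat and 26024012 to 35417607 with the combination. The share of reads in no gene was 19.7% ± 0.764 (SD, n = 3) under DMSO, 24.6% ± 0.961 with ipatasertib, 18.4% ± 0.501 with tazemetostat and 23.8% ± 0.923 with the combination. Of 23228 genes, 14874 were expressed enough to be tested. The first principal component of log2 CPM held 53.7% of the variance and placed DMSO and the combination at opposite ends. The second component, with 28.5%, placed ipatasertib and tazemetostat at opposite ends. Changes below are log2 fold changes from the edgeR quasi-likelihood fit over 3 libraries per group, given with a standard error (SE). Adjusted p-values are from the F-test of that fit with Benjamini-Hochberg adjustment. The changes are relative to TMM scaling. The SE was computed back from that test, as the size of the log2 change divided by the square root of F. It is approximate, and for large changes of genes with few counts it can fall below counting error. Scaling by total counts alone, chosen after seeing the data, moved the median of all genes by 0.12 with ipatasertib, 0.07 with tazemetostat and 0.14 with the combination, each against DMSO.

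**Figure D1:**
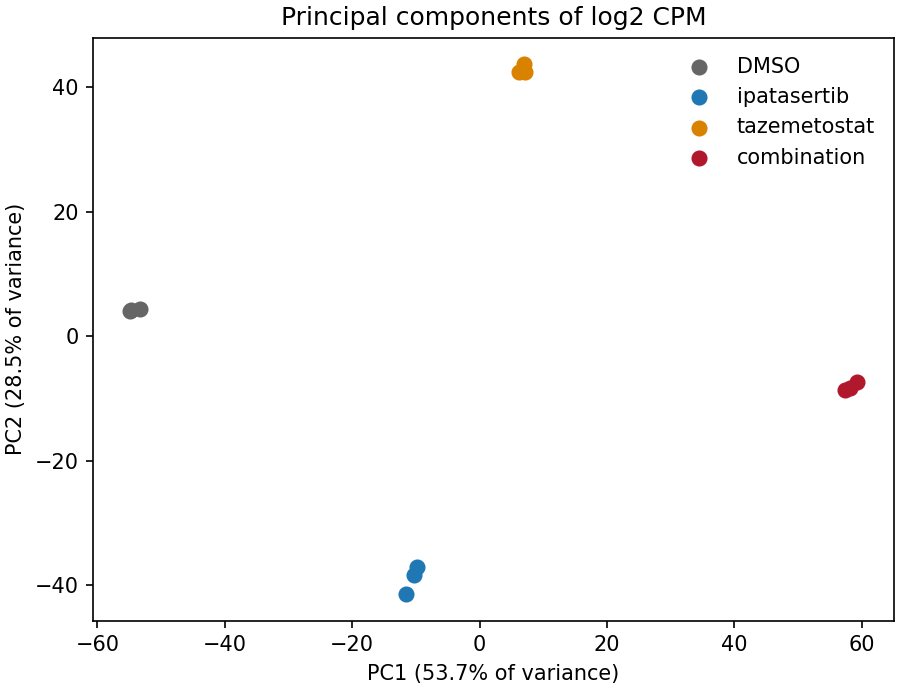
Each point is 1 library, placed by its scores on the first 2 principal components of log2 CPM, with the share of variance on each axis. The 3 libraries of each group lie together, and the first component, with 53.7% of the variance, runs from DMSO to the combination.

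Ipatasertib against DMSO shows what the AKT inhibitor did alone within 24 h. PDK4, the kinase that shuts off pyruvate dehydrogenase, rose 8.03-fold (log2 change 3.01, SE 0.11, n = 3 per group), from 1.93 ± 0.0858 to 15.5 ± 0.850 CPM (SD). KLHL24, a ubiquitin ligase adaptor, rose by 2.71 (SE 0.09), GBP2, an interferon-inducible GTPase, by 2.86 (SE 0.09), and ABCG1, a cholesterol exporter, by 2.95 (SE 0.15). The keratins of basal epithelium fell, with KRT5 going from 633 ± 19.8 to 146 ± 6.11 CPM, 4.32-fold lower (log2 change -2.11, SE 0.07). KRT14, KRT6A, KRT16 and KRT17 changed by -2.68 (SE 0.10), -2.44 (SE 0.07), -2.33 (SE 0.09) and -2.08 (SE 0.07), values that are uncertain because these genes have near-identical copies. F3, the tissue factor that starts coagulation, changed by -2.41 (SE 0.06). CCND1, the cyclin of the G1 phase, changed by -1.28 (SE 0.06), and BMF, a pro-apoptotic member of the BCL2 family, rose 3.01-fold (log2 change 1.59, SE 0.09). Adjusted p for these genes in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment lay between 2.16e-16 for F3 and 3.5e-11 for BMF.

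In the PI3K-AKT-FOXO feedback list, of genes that FOXO factors induce and AKT restrains by inhibiting FOXO, 22 of 29 rose, 4 fell and 3 did not pass (camera adjusted p = 4.48e-20, and 0.00552 with an estimated correlation). They included TXNIP at 1.38 (SE 0.05), an inhibitor of glucose uptake, CITED2 at 1.55 (SE 0.06), a transcriptional coregulator, and ERBB3 at 0.73 (SE 0.06), a receptor kinase. Of 25 autophagy and lysosome genes, 21 rose and 2 fell (camera adjusted p = 6.43e-10, and 0.044 with an estimated correlation). Among them were WIPI1 at 1.60 (SE 0.08) and GABARAPL1 at 1.01 (SE 0.07), which act in autophagosome formation, and SQSTM1 at 1.29 (SE 0.07), the cargo receptor. Ribosome biogenesis fell, with 21 of 22 genes lower and the nucleolar proteins NOP56 at -0.79 (SE 0.05) and NOLC1 at -0.74 (SE 0.05) among them (camera adjusted p = 1.41e-12, and 0.00552 with an estimated correlation). DNA replication and S-phase genes fell too, 27 of 30 being lower and 1 higher, as with the replication factors MCM10 at -0.83 (SE 0.06) and CDC6 at -0.83 (SE 0.06), at a camera adjusted p = 1.17e-08, and 0.0254 with an estimated correlation. Of 29 basal and myoepithelial markers, 18 fell, led by the keratins above, and 6 rose (camera adjusted p = 6.82e-14, and 0.00984 with an estimated correlation).

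Mitotic genes fell in 21 of 26 cases, among them CDC20 at -0.90 (SE 0.06), the activator of the anaphase-promoting complex, and PLK1 at -0.72 (SE 0.05), with camera adjusted p = 1.17e-08 but adjusted p = 0.192 with an estimated correlation. Of 17 glycolysis genes 14 fell and 1 rose, as with PGK1 at -0.56 (SE 0.05) and LDHA at -0.54 (SE 0.06), at camera adjusted p = 0.000555 but adjusted p = 0.401 with an estimated correlation. In the epithelial-mesenchymal transition list 17 of 27 fell and 4 rose, with CYR61 at -1.43 (SE 0.05) and TNC at -1.13 (SE 0.06), both secreted matrix proteins (camera adjusted p = 6.46e-06, but adjusted p = 0.0732 with an estimated correlation). Of the markers of other cell types, 7 of 10 rose and 3 fell without a call for the list (camera adjusted p = 0.736). The collagen gene COL3A1 changed by -1.21 (SE 0.10) there, while DCN, the matrix proteoglycan decorin, changed by 0.41 (SE 0.09). The luminal list had 8 genes higher and 8 lower of 22, with ELF3 at 0.99 (SE 0.08) and GATA3 at 0.59 (SE 0.06), luminal transcription factors, against KRT8 at -0.70 (SE 0.07). Adjusted over the list alone, the counts of these lists were the same except for 23 mitotic genes lower and 2 glycolysis genes higher.

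In all, 8040 genes changed, 3771 higher and 4269 lower, and 674 rose and 313 fell more than 2-fold. The higher share was 46.9%, but 63.1% when libraries were scaled by total counts alone. The test against a 1.5-fold change called 1089 genes.

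**Figure D2:**
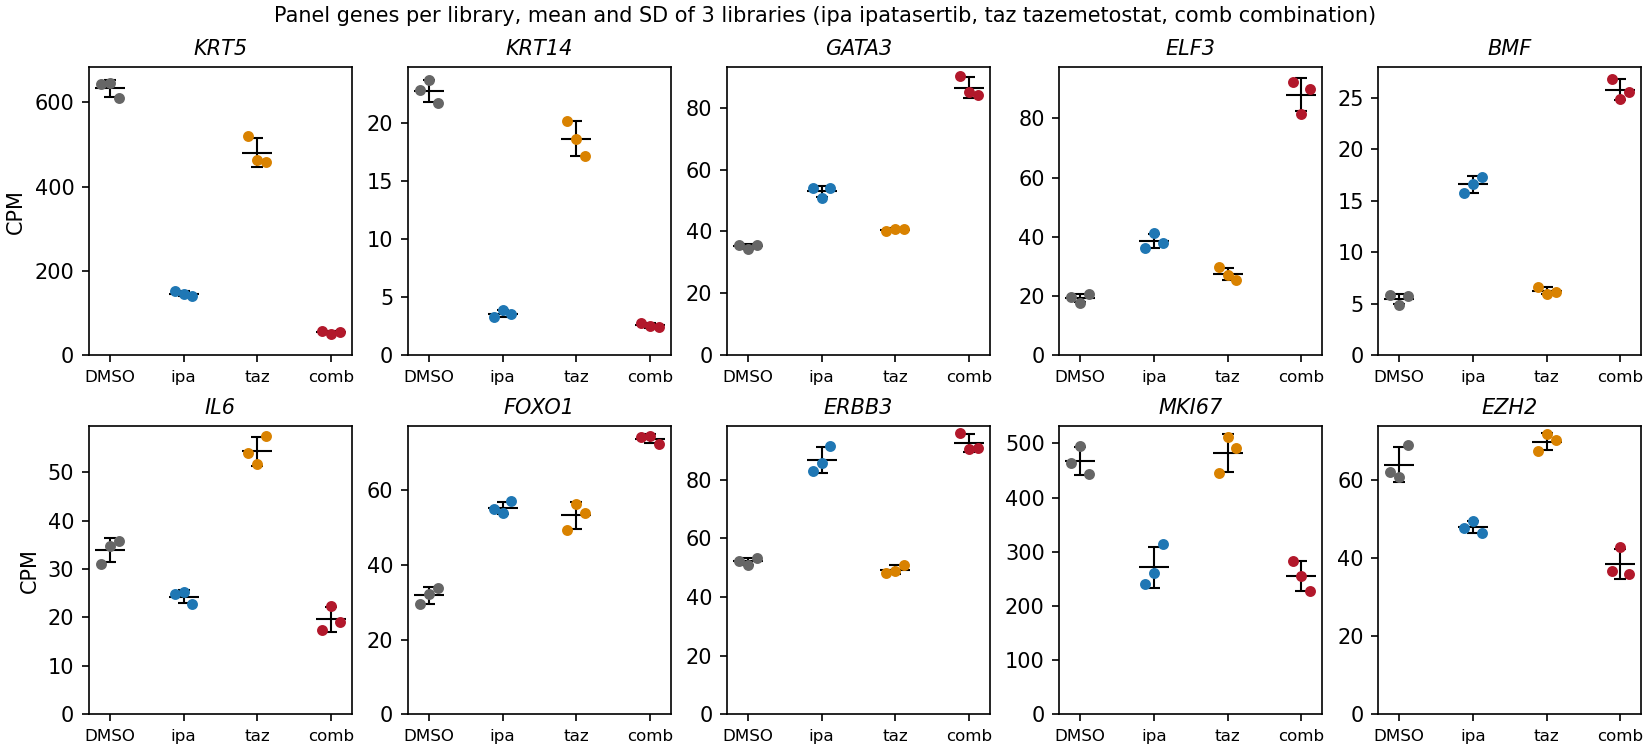
CPM of 10 genes of the preset panel in each library, with points for the libraries, bars for the mean and whiskers for the SD of 3 libraries per group. KRT5 falls from a mean of 633 CPM under DMSO to 54.6 CPM in the combination, while ELF3 rises from 19.3 to 87.9 CPM. The keratins KRT8 and KRT18, also of the preset panel, are not drawn. They fall in the combination, with log2 changes of -0.76 and -0.51 against DMSO.

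Tazemetostat against DMSO shows what the EZH2 inhibitor did alone. The largest rises were in genes with low levels under DMSO. B3GAT1, the enzyme that makes the HNK-1 carbohydrate, rose 35.8-fold (log2 change 5.16, SE 0.16, n = 3 per group), and IGFBP5, a secreted binding protein of insulin-like growth factors, rose 20.5-fold from 3.41 ± 0.331 to 69.3 ± 3.27 CPM (log2 change 4.36, SE 0.11). HSPB8, a small heat shock protein, TIMP3, an inhibitor of metalloproteinases, and F2R, the thrombin receptor, rose by 3.80 (SE 0.16), 3.73 (SE 0.12) and 3.34 (SE 0.12). The fibrillar collagen gene COL3A1 was 13.7-fold lower (log2 change -3.78, SE 0.11) and COL1A1 went from 424 ± 24.3 to 86.5 ± 4.74 CPM (log2 change -2.29, SE 0.09). THBS1, the matrix glycoprotein thrombospondin 1, changed by -2.31 (SE 0.06), and CREB3L1, a transcription factor of collagen genes, by -2.30 (SE 0.10). Adjusted p for these genes in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment lay between 7.02e-16 for IGFBP5 and 3.71e-13 for CREB3L1.

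In the epithelial-mesenchymal transition list 22 of 27 genes fell and none rose, with a median of -0.91, at camera adjusted p = 7.62e-40, and 0.000708 with an estimated correlation. ITGA5, the fibronectin receptor subunit, changed by -1.36 (SE 0.07) and VIM, the intermediate filament vimentin, by -1.08 (SE 0.06). The markers of other cell types moved the same way, 5 of 10 being lower and none higher (camera adjusted p = 1.03e-08, and 0.00259 with an estimated correlation). The fibroblast markers among them were COL3A1, DCN, from 98.8 ± 8.06 to 24.6 ± 1.19 CPM, and LUM, the matrix proteoglycan lumican, at -2.43 (SE 0.13). COL1A2, with few counts at 0.622 CPM under DMSO, was lower too, at -2.56 (SE 0.50). Other developmental transcription factors rose, with 35 of 55 higher and 4 lower (camera adjusted p = 8.34e-09, and 0.0194 with an estimated correlation). A member silent under DMSO passed the filter only if a treatment raised it, and could then only rise. This holds for every list against DMSO, so part of such rises may reflect the filter. How many members it concerns was not counted. LHX2, ALX4 and FOXQ1 rose by 2.96 (SE 0.15), 1.52 (SE 0.08) and 1.85 (SE 0.10). Of 23 HOX genes 7 rose and 2 fell, with no call for the list (camera adjusted p = 0.241), and its median of -0.03 and mean of 0.97 differed in sign. HOXB7 and HOXD13 rose from 20 and 6 counts over the 3 DMSO libraries to 181 and 167 counts with tazemetostat.

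Cholesterol synthesis genes rose in 20 of 25 cases and none fell (camera adjusted p = 1.03e-08, and 0.00579 with an estimated correlation). INSIG1, a sterol sensor, rose by 1.31 (SE 0.07) and HMGCS1, an early enzyme of the pathway, by 0.99 (SE 0.06). The fatty acid synthesis list had 6 of 13 higher and 1 lower, led by the desaturase SCD at 1.21 (SE 0.06), at camera adjusted p = 0.0197 but adjusted p = 0.187 with an estimated correlation. Of 17 milk and alveolar secretion genes only 8 passed the filter, and 6 of those rose (camera adjusted p = 0.000511, but adjusted p = 0.128 with an estimated correlation). Among them were LCN2, lipocalin 2, at 0.99 (SE 0.07) and PLIN2, a lipid droplet protein, at 0.88 (SE 0.08). Of 33 interferon-stimulated genes 16 rose and 1 fell, with OAS1 at 1.65 (SE 0.19) and IFITM1 at 0.74 (SE 0.08). That list was called at camera adjusted p = 0.0271, but adjusted p = 0.595 with an estimated correlation, and adjusted p = 0.0896 without tazemetostat A and combination B. Antigen presentation genes went both ways, 6 higher and 6 lower of 23 (camera adjusted p = 0.983), and the median of -0.04 and mean of 0.87 differed in sign. HLA-B, which shares reads with near-identical HLA genes and is uncertain, rose by 0.57 (SE 0.07), while the peptide transporter TAP2 changed by -0.64 (SE 0.08). The ERK feedback and immediate early list had 15 of 27 higher and 2 lower, with DUSP6, a phosphatase of ERK, at 0.76 (SE 0.08), at camera adjusted p = 0.0252 but adjusted p = 0.49 with an estimated correlation, and adjusted p = 0.062 without tazemetostat A and combination B.

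The mRNA of EZH2 itself was 64.0 ± 4.41 CPM under DMSO and 69.8 ± 2.17 CPM with tazemetostat, a change of 0.13 (SE 0.07) that did not pass. Of 11 PRC2 subunit genes 2 were higher and 1 lower, and 0 of each when adjusted over the list alone (camera adjusted p = 0.983). In the PI3K-AKT-FOXO feedback list 14 of 29 rose and 3 fell, with INSR, the insulin receptor, at 1.75 (SE 0.10) and FOXO1 at 0.74 (SE 0.07), at camera adjusted p = 0.0197 but adjusted p = 0.375 with an estimated correlation. For ribosome biogenesis 10 of 22 fell and none rose, as with POLR1A at -0.46 (SE 0.07), at camera adjusted p = 0.0252 but adjusted p = 0.222 with an estimated correlation. DNA replication and S-phase genes had 9 higher and 2 lower of 30 (camera adjusted p = 0.348), with CCNE1, cyclin E1, at 0.81 (SE 0.07). Adjusted over the list alone, counts differed for fatty acid synthesis with 2 lower, the developmental factors with 6 lower and S phase with 8 higher, and were the same for the other lists given here.

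Tazemetostat changed 6849 genes, 3737 higher and 3112 lower, and 995 rose and 159 fell more than 2-fold. The higher share was 54.6%, but 69.6% under scaling by total counts alone, and more genes were lower than higher without DMSO B (2707 higher, 2935 lower), tazemetostat A (3424 and 3788), tazemetostat B (2844 and 2939) or tazemetostat C (2793 and 2843). The test against a 1.5-fold change called 1094 genes.

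The combination against DMSO gave the largest changes. IGFBP5 rose 89.7-fold to 304 ± 35.4 CPM (log2 change 6.49, SE 0.12, n = 3 per group), CHRM3, a muscarinic acetylcholine receptor, 49.6-fold (log2 change 5.63, SE 0.13) and GBP2 22.3-fold (log2 change 4.48, SE 0.09). KRT5 fell 11.6-fold to 54.6 ± 4.15 CPM (log2 change -3.53, SE 0.07), and COL3A1 32.1-fold to 0.961 ± 0.197 CPM (log2 change -5.01, SE 0.14). The luminal transcription factors ELF3 and GATA3 rose 4.55-fold and 2.45-fold, and BMF rose 4.68-fold. In contrast, the keratins KRT8 and KRT18 of the preset panel changed by -0.76 (SE 0.07) and -0.51 (SE 0.07). EZH2 changed by -0.73 (SE 0.07) and the proliferation marker MKI67 by -0.87 (SE 0.09). Adjusted p for these genes in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment lay between 1.11e-18 for IGFBP5 and 4.31e-06 for KRT18.

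PI3K-AKT-FOXO feedback genes rose in 24 of 29 cases and 3 fell, with PDK4 at 4.41 (SE 0.10) and IRS2, an adaptor of the insulin receptor, at 2.22 (SE 0.06) (camera adjusted p = 7.14e-17, and 0.00871 with an estimated correlation). Ribosome biogenesis fell in 21 of 22 genes (camera adjusted p = 2.32e-10, and 0.00871 with an estimated correlation) and DNA replication and S phase in 28 of 30, with MCM10 at -1.25 (SE 0.06) (camera adjusted p = 4.19e-10, and 0.0261 with an estimated correlation). Basal and myoepithelial markers fell in 19 of 29 cases and 9 rose (camera adjusted p = 2.88e-08, and 0.0261 with an estimated correlation). The epithelial-mesenchymal transition list had 23 of 27 lower and 2 higher, with COL4A1, a basement membrane collagen, at -2.19 (SE 0.08) (camera adjusted p = 1.52e-16, and 0.00678 with an estimated correlation). The markers of other cell types had 4 higher and 5 lower of 10 at camera adjusted p = 0.0462, but adjusted p = 0.131 with an estimated correlation and 0.0777 without tazemetostat A and combination B. Their median of -0.07 turned to 0.07 under scaling by total counts alone and to 0.52 without those libraries, while the test kept its direction.

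Luminal markers rose in 13 of 22 cases and 7 fell (camera adjusted p = 0.034, but adjusted p = 0.144 with an estimated correlation). Of 27 mammary involution genes 13 rose and 9 fell (camera adjusted p = 0.0433, but adjusted p = 0.368 with an estimated correlation). LCN2 at 1.53 (SE 0.07) and TIMP1, a metalloproteinase inhibitor, at 1.12 (SE 0.07) rose beside IGFBP5 and BMF. IL6 of the same list held 19.6 ± 2.56 CPM (SD, n = 3) in the combination against 33.9 ± 2.46 under DMSO. STAT3 lay near 0, from -0.0572 to 0.0564 over the fits without 1 library. Of the 8 milk and alveolar secretion genes that passed the filter, 6 rose and none fell (camera adjusted p = 0.000534, but adjusted p = 0.105 with an estimated correlation). Autophagy and lysosome genes rose in 20 of 25 cases and 3 fell, with WIPI1 at 2.57 (SE 0.08) (camera adjusted p = 6.18e-07, but adjusted p = 0.0974 with an estimated correlation). Mitotic genes fell in 23 of 26 cases (camera adjusted p = 8.17e-08, but adjusted p = 0.149 with an estimated correlation), and glycolysis genes in 14 of 17 with 2 higher (camera adjusted p = 0.00084, but adjusted p = 0.282 with an estimated correlation). Other developmental transcription factors rose in 33 of 55 cases and 8 fell (camera adjusted p = 0.000307, but adjusted p = 0.101 with an estimated correlation). The ERK feedback and immediate early list had 17 of 27 higher and 7 lower, with SPRY4 and SPRED2, inhibitors of ERK signalling, at 1.46 (SE 0.07) and 1.02 (SE 0.06) (camera adjusted p = 0.0433, but adjusted p = 0.368 with an estimated correlation).

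Several lists had many changed members and no call. In the BCL2 family 5 of 15 rose and 5 fell, with the pro-apoptotic genes BBC3 at 1.38 (SE 0.12) and HRK at 2.29 (SE 0.22) beside the anti-apoptotic BCL2 at 1.20 (SE 0.15) (camera adjusted p = 0.368), and the median of -0.10 and mean of 0.36 differed in sign. The ATF4 and amino acid response had 11 higher and 9 lower of 25, with NUPR1, a stress-induced regulator, at 2.88 (SE 0.09) and PSAT1, an enzyme of serine synthesis, at -0.91 (SE 0.06) (camera adjusted p = 0.854), and its median of 0.20 and the direction of the test differed in sign. NF-kB and inflammatory cytokine genes had 5 higher and 10 lower of 26, with IL1B at -1.32 (SE 0.07) (camera adjusted p = 0.197), a median of -0.11 and a mean of 0.06. Adjusted over the list alone, counts against DMSO in the combination were 22 lower for ribosome biogenesis, 24 lower for mitosis, 10 higher for the basal list and 7 lower for the BCL2 family, and were the same for the other lists given here.

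In all 10565 genes changed, 5435 higher and 5130 lower, and 2055 rose and 760 fell more than 2-fold. The higher share was 51.4%, but 62.6% under scaling by total counts alone. The test against a 1.5-fold change called 3849 genes.

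**Figure D3:**
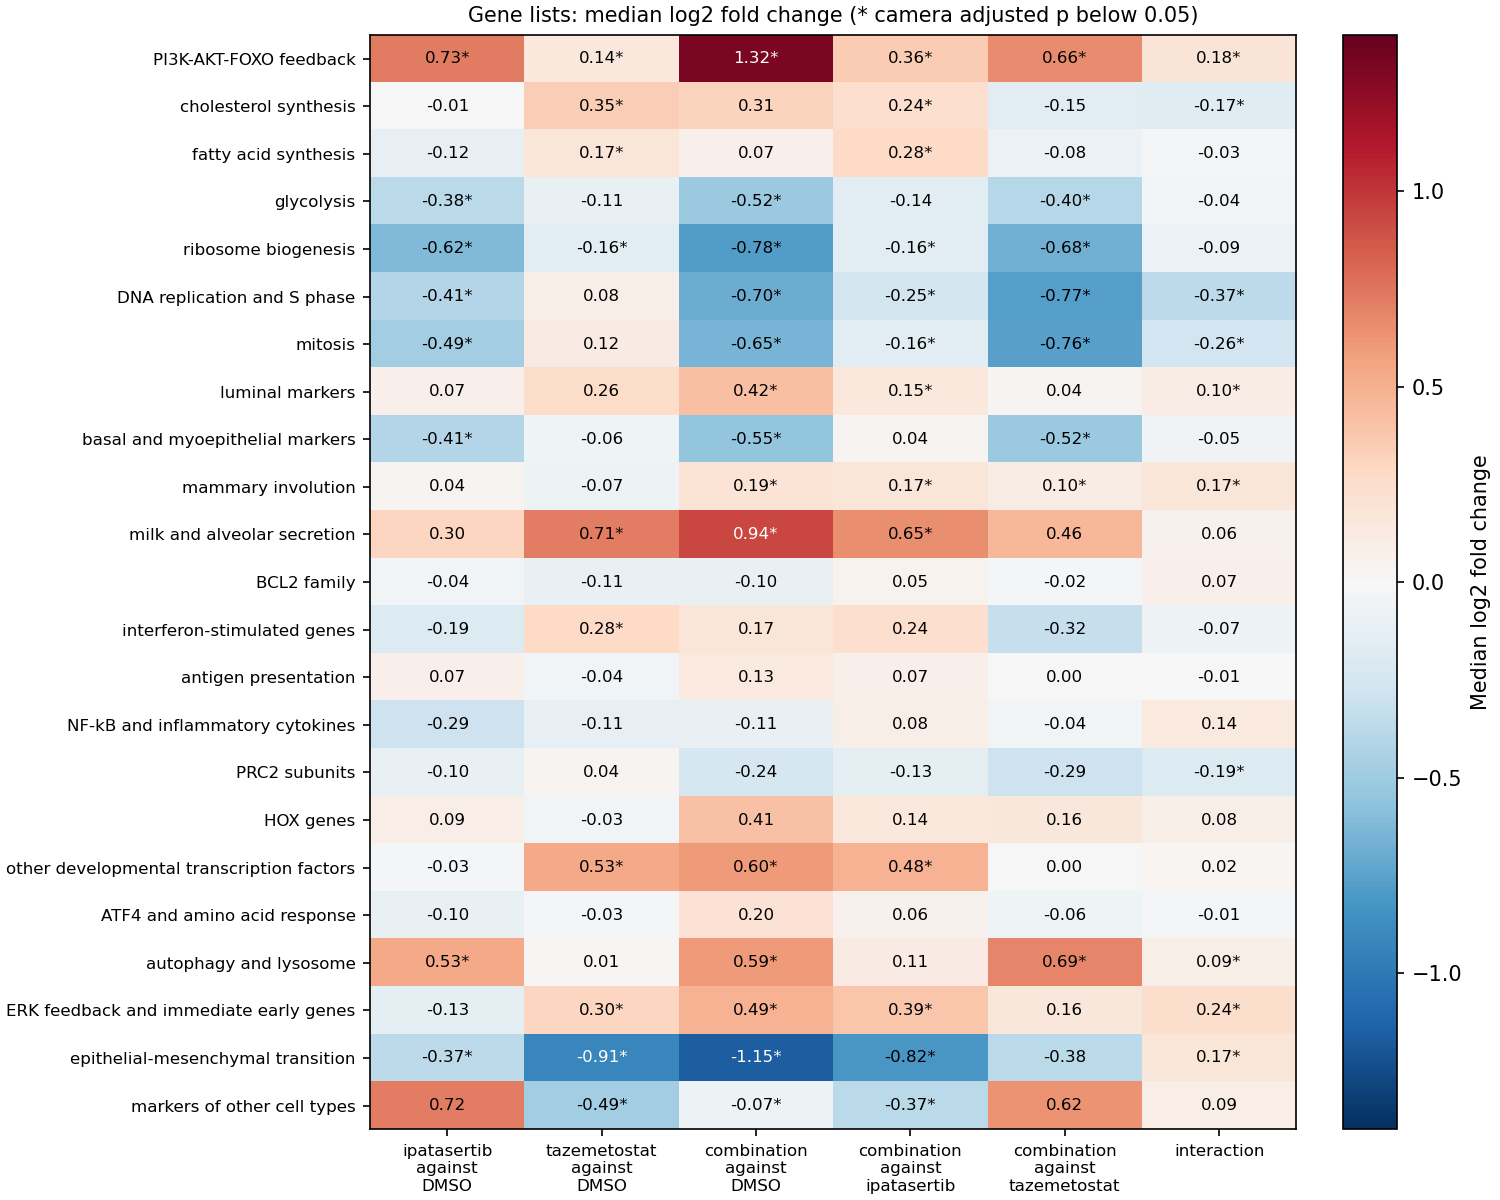
Median log2 fold change of the members of each of the 23 gene lists in each comparison, by colour and as a number, with a star where the camera adjusted p at the preset correlation passed the threshold. Of the 63 starred values, 29 also passed with an estimated correlation, and the epithelial-mesenchymal transition list reached -0.91 with tazemetostat and -1.15 in the combination, each against DMSO.

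The combination against ipatasertib shows what tazemetostat added to the AKT inhibitor. IGFBP5 rose 66.0-fold (log2 change 6.04, SE 0.11, n = 3 per group), TIMP3 20.7-fold (log2 change 4.37, SE 0.13) and ELF3 2.28-fold (log2 change 1.19, SE 0.08). COL3A1 fell 13.9-fold (log2 change -3.79, SE 0.15), DCN 4.26-fold (log2 change -2.09, SE 0.10) and KRT5 2.68-fold (log2 change -1.42, SE 0.07). In the epithelial-mesenchymal transition list 22 of 27 fell and 2 rose, and 24 fell when adjusted over the list alone (camera adjusted p = 9.7e-24, and 0.00205 with an estimated correlation). The markers of other cell types moved beside it with 4 of 10 lower, the fibroblast markers COL3A1, DCN and LUM among them, and 3 higher (camera adjusted p = 1.03e-05, and 0.0137 with an estimated correlation). ERK feedback and immediate early genes rose in 20 of 27 cases, or 21 adjusted over the list alone, and 1 fell. EGR1, an immediate early transcription factor, rose by 1.86 (SE 0.11) and HBEGF, a ligand of the EGF receptor, by 1.48 (SE 0.10) (camera adjusted p = 1.23e-09, and 0.0436 with an estimated correlation). DNA replication and S-phase genes fell in 25 of 30 cases, or 26 adjusted over the list alone, and 1 rose, with TYMS, thymidylate synthase, at -0.71 (SE 0.08) (camera adjusted p = 5.17e-06, and 0.0436 with an estimated correlation). Luminal markers rose in 10 of 22 cases and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.000448, and 0.0429 with an estimated correlation). In all 5823 genes changed in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3248 higher and 2575 lower, or 3014 and 3332 without a filter and 3028 and 2923 with DESeq2 size factors, and 1121 genes passed the test against a 1.5-fold change.

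The combination against tazemetostat shows what ipatasertib added to the EZH2 inhibitor. PDK4 rose 13.2-fold (log2 change 3.72, SE 0.09, n = 3 per group), GBP2 12.1-fold (log2 change 3.60, SE 0.08) and BMF by 2.04 (SE 0.08). KRT5 fell 8.78-fold (log2 change -3.13, SE 0.07), CPA4, a carboxypeptidase, 5.18-fold (log2 change -2.37, SE 0.08), and the cytokine gene IL6 changed by -1.47 (SE 0.09). All 30 DNA replication and S-phase genes fell, with RRM2, a subunit of ribonucleotide reductase, at -1.21 (SE 0.06) (camera adjusted p = 1.06e-19, and 0.00456 with an estimated correlation). Of 29 PI3K-AKT-FOXO feedback genes 23 rose and 2 fell (camera adjusted p = 4.79e-21, and 0.00452 with an estimated correlation), and of 22 ribosome biogenesis genes 21 fell (camera adjusted p = 3.73e-11, and 0.00456 with an estimated correlation). Basal and myoepithelial markers fell in 17 of 29 cases and 6 rose (camera adjusted p = 2.24e-10, and 0.017 with an estimated correlation). Autophagy and lysosome genes rose in 23 of 25 cases and 2 fell (camera adjusted p = 2.24e-10, and 0.04 with an estimated correlation). All 26 mitotic genes fell (camera adjusted p = 1.09e-14, but adjusted p = 0.0666 with an estimated correlation). These counts were the same when adjusted over the list alone. In all 9020 genes changed in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 4434 higher and 4586 lower, or 5122 and 3857 under scaling by total counts alone and 4557 and 4476 with DESeq2 size factors, and 1999 genes passed the test against a 1.5-fold change.

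In the combination 3082 genes stood apart from all 3 other groups in 1 direction, 1629 higher and 1453 lower, of which 282 and 34 differed more than 2-fold from each. The balance turned to 1542 higher and 1613 lower with DESeq2 size factors, 1458 and 1839 without a filter and 1393 and 1642 with the DESeq2 test, and was 1837 and 1145 under scaling by total counts alone. CHRM3 was highest in the combination, at 55.9 ± 2.63 CPM (SD, n = 3) against 1.15 ± 0.268 under DMSO, 5.74 ± 0.416 with ipatasertib and 9.95 ± 0.946 with tazemetostat. MGP, the matrix Gla protein, stood at 196 ± 9.68 CPM against 14.9 ± 1.38, 43.5 ± 0.990 and 45.1 ± 1.68 CPM in the same order. ODZ2, a teneurin, was lowest at 15.7 ± 1.38 CPM against 198 ± 3.38, 83.5 ± 1.78 and 56.0 ± 4.74 CPM, and IL7R, the interleukin 7 receptor, at 5.64 ± 0.338 against 49.5 ± 5.45, 15.9 ± 1.07 and 19.9 ± 2.59 CPM. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the largest adjusted p among the pairwise tests of these genes was 4.15e-09, for IL7R against ipatasertib.

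The responses to the inhibitors alone overlapped. In the same direction 3226 genes were called, 1554 higher and 1672 lower with both, where independent lists would share 947 and 893. In opposite directions 873 genes were called, 350 higher with ipatasertib and lower with tazemetostat and 523 the reverse, where independent lists would share 789 and 1073. FGFBP1, a carrier of fibroblast growth factors, changed by -1.66 (SE 0.08, n = 3 per group) with ipatasertib and 1.26 (SE 0.07) with tazemetostat, and CBLB, a ubiquitin ligase, by 1.15 (SE 0.07) and -1.06 (SE 0.07). SORBS2, an adaptor protein, changed by 2.51 (SE 0.07) and -1.11 (SE 0.08). Across genes, which are not independent replicates, the log2 changes had a correlation of 0.289 and a covariance of 0.121. Unchanged groups simulated against the same DMSO libraries gave a correlation of 0.503 and a covariance of 0.0120 over 20 draws. The observed covariance exceeded the simulated one by 0.109. The draws gave 0 shared calls, but with no gene changed almost none can be called. That 0 therefore does not measure how sharing the libraries moves calls where many genes change. No split of the 3 DMSO libraries leaves 2 as controls for each inhibitor, so part of the excess of shared calls over independent lists may come from sharing them. Under scaling by total counts alone the shared calls were 2397 higher and 932 lower.

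The interaction asks where the combination departed from the sum of the log2 changes with each inhibitor. TNFRSF19, a receptor of the TNF family, was above the sum by 1.80 (SE 0.15, n = 3 per group), IGFBP5 by 1.69 (SE 0.17), EGR1 by 1.43 (SE 0.15) and THBD, thrombomodulin, by 1.42 (SE 0.14). KRT5 was below it by 1.02 on the log2 scale (interaction -1.02, SE 0.09), and the cytokine genes IL33 and IL6 had interactions of -1.03 (SE 0.13) and -0.99 (SE 0.12). GATA3 and ELF3 were above the sum by 0.50 (SE 0.08) and 0.68 (SE 0.11). The adjusted p of these genes in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment lay between 8.44e-07 for TNFRSF19 and 0.00146 for GATA3.

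DNA replication and S-phase genes were below the sum in all 30 cases, with a median of -0.37, and 17 passed, or 24 adjusted over the list alone (camera adjusted p = 1.95e-24, and 0.00384 with an estimated correlation). RRM2 and CCNE2, cyclin E2, had interactions of -0.61 (SE 0.09) each, and MCM10 -0.50 (SE 0.08). The count of 17 was 9 without DMSO B, 7 without ipatasertib A, 8 without ipatasertib B, 9 without tazemetostat B and 9 without combination C. Of 26 mitotic genes 5 were below the sum and none above, or 17 below adjusted over the list alone, with CDK1, the mitotic kinase, at -0.62 (SE 0.11) (camera adjusted p = 8.46e-12, but adjusted p = 0.109 with an estimated correlation). The ERK feedback and immediate early list had 6 of 27 above and none below, or 11 above and 1 below adjusted over the list alone, with SPRY4 at 0.96 (SE 0.10) and HBEGF at 1.03 (SE 0.14) (camera adjusted p = 3.24e-10, but adjusted p = 0.06 with an estimated correlation). The epithelial-mesenchymal transition list had 7 of 27 above and 1 below, or 9 and 2 adjusted over the list alone, with THBS1 at 0.95 (SE 0.08) and TNC at 0.63 (SE 0.08) (camera adjusted p = 2.26e-06, but adjusted p = 0.06 with an estimated correlation). Of the 10 lists called in the interaction at the preset correlation, DNA replication and S phase alone was also called with an estimated correlation.

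**Figure D4:**
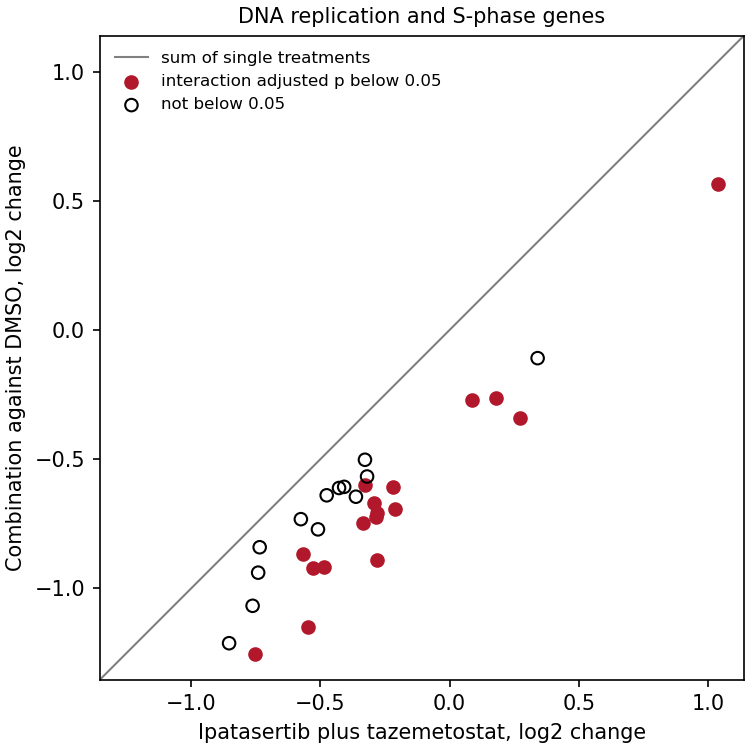
For each of the 30 DNA replication and S-phase genes, the log2 change in the combination against DMSO on the vertical axis and the sum of the log2 changes with ipatasertib and tazemetostat on the horizontal axis, with filled points for an interaction past the threshold. All 30 points lie below the line of equality, 17 of them filled.

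The interaction called 539 genes, 278 above the sum and 261 below, with 51.6% above, but 27.8% under scaling by total counts alone. The number depended on single libraries. It was 329 without DMSO A, 278 without DMSO B, 243 without ipatasertib A, 276 without ipatasertib B, 1046 without tazemetostat A, 313 without tazemetostat B, 282 without tazemetostat C, 2443 without combination B and 274 without combination C. Leaving out tazemetostat A and combination B together, which stood apart in their groups, gave 4766 genes. It was 905 without a filter, 943 with DESeq2 and 16 against a 1.5-fold change.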

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

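The tests of library scaling for each pattern below, and those of fibroblast markers and COL1A2, were chosen only after the result was seen.

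The effect of ipatasertib differed with and without tazemetostat, by the test of the interaction, in 539 genes. Of 50 splits of the 12 libraries, 2 gave as many genes, the real one among them. The other gave 4340 genes and placed the 3 DMSO libraries together in 1 group, which points to a structure of the samples, and the next highest gave 0. The other splits mix treatments, whose differences enter the spread within groups, so these counts do not settle whether chance gave the 539. The count ran from 243 without ipatasertib A to 2443 without combination B, and was 329 without DMSO A, 278 without DMSO B, 276 without ipatasertib B, 1046 without tazemetostat A, 313 without tazemetostat B, 282 without tazemetostat C and 274 without combination C.

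The same test set apart TNFRSF19 (1.80 on the log2 scale), IGFBP5 (1.69), EGR1 (1.43), THBD (1.42), S1PR1 (1.36), ELF3 (0.68) and GATA3 (0.50), which lay above the sum of the changes with each inhibitor. Below it lay IL33 (-1.03), KRT5 (-1.02), IL6 (-0.99) and CNTNAP2 (-0.97). Further genes passed by less. IGF2BP3 (-0.95) had an adjusted p of 0.0532 without ipatasertib A. TNFAIP6 (-0.88) and EZH2 (-0.44) were no longer called without each of DMSO A, DMSO B, ipatasertib A, ipatasertib B, tazemetostat B, tazemetostat C and combination C, with adjusted p from 0.0564 to 0.0728 and from 0.0554 to 0.0791. BMF (0.45) was no longer called with DESeq2 size factors, without a filter, under scaling by total counts alone, or without each library but DMSO B, tazemetostat A and combination B, with adjusted p from 0.0507 to 0.140. STAT3 (0.33) was no longer called without a filter or without each of DMSO A, DMSO B, DMSO C, ipatasertib A, ipatasertib B, ipatasertib C, tazemetostat C and combination C, with adjusted p from 0.0516 to 0.0862.

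In all 30 DNA replication and S-phase genes the combination lay below the sum of the changes with each inhibitor, with a median of -0.37 on the log2 scale, and 17 passed the test of the interaction. A scaling factor moves all genes of a library alike, and the median of the list minus that of all tested genes was -0.37, which argues against scaling. Against any 1 library as the cause stand a median of -0.34 at the nearest to 0 and a largest camera adjusted p of 2.02e-18, or 0.0261 with an estimated correlation, over 12 fits that each left out 1, though the number passing fell to 7 without ipatasertib A, 8 without ipatasertib B and 9 without each of DMSO B, tazemetostat B and combination C. Expression level is argued against by 10000 random lists matched on it, of which 0 percent had a median as low and the lowest reached -0.15. An effect of both inhibitors together on these genes stays open as a biological hypothesis, found and tested on the same data, while the interaction of the proliferation marker MKI67 was -0.14 (adjusted p = 0.601) and the mitosis list had a median of -0.26 (camera adjusted p = 8.46e-12, but adjusted p = 0.109 with an estimated correlation).

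The epithelial-mesenchymal transition list, which holds several collagen and matrix genes, fell with tazemetostat with a median of -0.91. The median nearest 0 over 2 other scalings was -0.84, and without tazemetostat A it was -0.97, which argues against scaling or that library as the whole cause. Fibroblasts would bring COL1A2 along with COL1A1 and DCN, but COL1A2 held 0.622 ± 0.253 CPM (SD, n = 3) under DMSO, 0.630% of DCN. This argues against a loss of contaminating fibroblasts, but not against fewer cells of a part of the line with little COL1A2. With tazemetostat COL1A2 changed by -2.56 (SE 0.50), near LUM at -2.43 and COL1A1 at -2.29, as a loss of cells that express these genes would give. Against that, COL3A1 and DCN differed by 1.77 (SE 0.149) on the log2 scale, and PDGFRB held 0.194 CPM under DMSO. An effect of tazemetostat within cells and a change in the share of such cells in the line were not told apart. Both stay open as biological hypotheses, found and tested on the same data.

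The share of reads in no gene was higher than the 19.7% of DMSO with ipatasertib, at 24.6%, and with the combination, at 23.8%, a signal outside the gene counts. With ipatasertib, 59 of 78 ribosomal protein genes, a set chosen after seeing the data, were higher and 5 lower, with a median of 0.31 (camera p = 2.51e-08, and p = 0.278 with an estimated correlation), while the ribosome biogenesis list had a median of -0.62. The median of the ribosomal protein genes minus that of all tested genes was 0.32, and the median of the biogenesis list nearest 0 over 2 other scalings was -0.50, which argue against scaling. Other genes of the same length had a median of -0.12. Length was the median over the annotated transcripts of a gene, which need not be the length of those expressed here. Those genes were also lower in expression, with a median of 106 CPM against 358 CPM for the ribosomal protein genes. Transcript length is therefore not settled by this. Reads shared with pseudogene copies were not tested, and both stay open beside an effect of ipatasertib.

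For the comparisons of 3 libraries with 3, the 10 splits were too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes, and the highest other gave 0, against 8040 for ipatasertib, 6849 for tazemetostat and 10565 for the combination against DMSO, 5823 for the combination against ipatasertib and 9020 against tazemetostat. The 3082 genes apart in the combination and the 3226 shared by both inhibitors were each reached in 1 of 50 splits, the real one, with a highest other of 0. Those splits also mix treatments, so a count of 0 is what their spread within groups gives, and chance is not excluded by them.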

How the results depend on the processing

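Scaling by total counts and the fits without both tazemetostat A and combination B, the libraries that stood apart, were chosen after seeing the data; the other alternatives were fixed before. Counts of changed genes stayed within 1.5 times the reported ones except as follows. Against a 1.5-fold change, a stricter question by construction, the counts were 1089 for ipatasertib, 1094 for tazemetostat and 3849 for the combination against DMSO, 1121 for the combination against ipatasertib, 1999 against tazemetostat and 16 for the interaction. The interaction also gave 905 without a filter, 943 with DESeq2 and 4766 without both libraries, and 243 to 2443 without 1 library. The cause was not tested. As deviations from their group means, tazemetostat A and combination B had a correlation of -0.339. Combination B had 0.207 with tazemetostat B and 0.184 with tazemetostat C. Deviations from a group mean cancel within the group, so these 2 values are tied to the -0.339 and are not separate observations. Without 1 library the other counts ran from 7009 to 7336 for ipatasertib, 5504 to 7212 for tazemetostat, 9930 to 10645 for the combination, 4855 to 6213 and 8093 to 9266 for the combination against ipatasertib and tazemetostat, 2405 to 3349 for genes apart in the combination and 2449 to 3481 for the overlap. Which direction held more genes turned under at least 1 alternative for every count of genes except the combination against DMSO. Among other cases it turned for ipatasertib without a filter (4071 higher, 3928 lower), for the combination against ipatasertib without a filter (3014 and 3332), for the interaction with DESeq2 (428 and 515) and for the overlap without a filter (1591 and 1581). Of 63 list calls, 29 were made with an estimated correlation, and fry called 100. The libraries held at least 22355242 gene counts, so genes with few counts have wide errors.

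Across all groups the replicate letters showed no general pairing of the libraries. The 18 correlations between libraries of the same letter ran from -0.0665 to 0.302, with a median of -0.00322, and 6 of 12 libraries were closest to their own letter. Of the 18, 2 exceeded 0.1, both between the groups with tazemetostat. They were 0.302 for tazemetostat A with combination A and 0.207 for tazemetostat B with combination B, so a structure shared by these groups is not excluded. Combination B was nearly as close to tazemetostat C, of another letter, at 0.184. With the letter as a block the counts were 8250, 7123 and 10698 against DMSO, 6035 and 9213 for the combination against ipatasertib and tazemetostat, 753 for the interaction, 3271 genes apart, an overlap of 3408 and 62 list calls.

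Of 10834 alternative values for 264 named genes, 10236 kept direction and side of the threshold, 396 no longer passed, 167 newly passed and 35 changed direction. Of the 396, 231 came from the test against a 1.5-fold change, a stricter question, and 137 from leaving out 1 library. The cause of the 35 changes of direction was not tested, and HLA-DMB aside these values lay near 0 on the log2 scale. With total counts they were PIK3R1, ipatasertib against DMSO 0.0278, STAT3, tazemetostat against DMSO 0.00309, STAT3, combination against DMSO 0.120 and TBK1, combination against tazemetostat 0.0174. With the stricter filter they were STAT3, combination against DMSO 0.0193 and TMEM173, interaction 0.00746, and without a filter TBK1, combination against ipatasertib -0.00770. Without both libraries they were STAT3, combination against DMSO 0.0572, KRT18, combination against ipatasertib 0.0263, TBK1, combination against ipatasertib -0.0781, AKT2, combination against tazemetostat 0.135 (adjusted p = 0.0173), AKT1, interaction 0.0842, TMEM173, interaction 0.0608 and CCND1, interaction 0.00796. Without 1 library the ranges were MKI67, tazemetostat against DMSO -0.0257 to 0.0666, STAT3, combination against DMSO -0.0572 to 0.0564, KRT18, combination against ipatasertib -0.106 to 0.0259, TBK1, combination against ipatasertib -0.0791 to 0.113, MKI67, combination against ipatasertib -0.189 to 0.0154, AKT2, combination against tazemetostat -0.0969 to 0.0534 and TBK1, combination against tazemetostat -0.118 to 0.0675. For the interaction they were HLA-DMB, interaction -4.24 to 0.0429 (the high end without ipatasertib A, with 0 counts under DMSO and 4 with ipatasertib, and -3.74 with all libraries, adjusted p = 0.295), AKT1, interaction -0.108 to 0.0316, TMEM173, interaction -0.0623 to 0.0629 and CCND1, interaction -0.0869 to 0.00121.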

Other observations

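Genes outside the lists were looked at only after the data were seen, so their values are given without a test of a theme. FTH1, the heavy chain of ferritin, which has many near-identical copies and is uncertain, changed by 1.43 (SE 0.05, n = 3 per group) with ipatasertib, 0.73 (SE 0.05) with tazemetostat and 2.18 (SE 0.05) with the combination. FTL, the light chain, changed by 0.65 (SE 0.07), 0.38 (SE 0.07) and 0.91 (SE 0.07). Both passed in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p of 0.000229 or less. The nuclear RNAs MALAT1 and NEAT1 changed by 0.60 (SE 0.12) and 0.62 (SE 0.11) with ipatasertib and by 0.91 (SE 0.13) and 1.13 (SE 0.11) with the combination, in the groups with the higher share of reads in no gene.

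Replication-dependent histone genes, most of whose transcripts carry no polyA tail and many of which have near-identical copies, summed to 155 ± 10.9 CPM (SD, n = 3) under DMSO, 205 ± 11.2 with ipatasertib, 219 ± 7.99 with tazemetostat and 276 ± 5.97 with the combination. Of 52 such genes, 14 were higher and 1 lower with ipatasertib, 24 higher and 0 lower with tazemetostat, and 24 higher and 0 lower with the combination.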
